A study of Rattus norvegicus with 36 samples.

How the data were processed

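Liver RNA of male Sprague Dawley rats was hybridised to Affymetrix 3′ expression arrays, 36 in all, with 6 arrays for vehicle and for each of 5 doses of TBPH (706, 70.6, 7.06, 0.71 and 0.07 mg/kg). Per the labels the rats were 7 weeks old at the start, were dosed by gavage at 5 ml/kg for 5 days and were killed the day after the last dose. The labels number the replicates but do not say that each array is a separate animal, so p-values measure the spread between these samples. The deposited table holds log2 values made by the authors, 1 per probe set and array, on the scale of RMA (background correction, quantile normalization between arrays and a summary per probe set). RMA and the affy package are named per the submitters' processing notes, with no versions given, and no genome build is named. The values ran from 1.86 to 14.77 with none missing, and no filter on probe sets was seen in the table.

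Of 31099 probe sets, 57 array controls were left out and 31042 were tested. The array annotation gave 1 gene symbol for 20826 probe sets, several symbols for 436 and none for 9780; only probe sets with 1 symbol were named as genes, giving 14217 genes, of which 4525 have more than 1 probe set. Of these, 20758 probe sets were matched by Entrez gene ID to current symbols, which changed 1 symbol. No positions are given, since the table names no build. Arrays give no read depth, and the number of arrays limits the precision. The median standard error of a log2 difference between a dose and vehicle was 0.08.

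Each comparison used limma 3.58.1 in R 4.3.3 on all 36 arrays with 1 mean per group (30 residual degrees of freedom), two-sided moderated tests and a Benjamini-Hochberg threshold of 0.05 over all probe sets of the comparison. The series' design text names R/maanova, which was not installed, and limma on all arrays was the nearest fit at hand. The comparisons were each dose against vehicle, a slope over dose rank, any difference among the 6 groups and 706 against 70.6 mg/kg. Each dose was compared with the same vehicle arrays, so results that recur at several doses are not independent of each other. In 20 simulations with 200 changed probe sets each, made by shuffling residuals, a change of 0.5 log2 was recovered in 85.5% of cases, 0.25 log2 in 20.0% and 1 log2 in 99.1%, with 4.61% false calls and no call of the wrong sign. These rates hold for that many changed probe sets, picked at random, at sizes from 0.25 to 1.5 log2. With fewer changed probe sets the adjusted threshold is stricter and recovery lower, which was not simulated. Genes with a larger standard error, such as Cyp7a1 (0.49 at 706 mg/kg against vehicle), would be recovered less often.

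A set of 31 gene lists for liver and for a phthalate ester, with marker lists of other cell types, was tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each gene, with adjustment over all 155 pairs of list and dose. The lists hold 602 measured members, and some genes stand in more than 1 list. An estimated correlation and fry were the alternatives; fry's directional p asks whether a list's genes move one way on balance and its mixed p whether they change either way, and neither compares a list with other genes. The adjusted p with an estimated correlation came out at 0.995 for each of the 16 called pairs. It therefore shows only that none of them passed, and it does not rank the lists. Members were counted after adjustment over all probe sets and also adjusted over the list alone. The latter was made separately in each of the 155 pairs, so some members can pass it by chance. Exact permutation tests were used for groups of 6 arrays and 100000 resamples for larger sets, all two-sided except tests on a sum of squares between groups.

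Named genes were chosen by a rule fixed before the data were examined, as were the comparisons, the tests, the lists and most of the alternative settings. The rule names the genes past the threshold with the largest changes and, at a dose where none passes, the 3 genes with the smallest p; a fixed panel at every dose; the 2 members with the smallest p in each list at 706 mg/kg; and the 10 genes with the smallest p for the slope and for any difference. Other list members were named as examples after their values were seen. The panel gene Cyp2b1 was not analysed here, since no probe set with its symbol alone was found in the table used, and 2 other panel genes are not reported here. The alternatives covered the arrays in the fit, a replicate block, the variance moderation, array weights, a filter on dim probe sets, normalization, 1 probe set per gene, thresholds, the dose scale and leaving out each array in turn. Pooled doses, the trend of the lists over dose, the tests of the whole profile, the fits without the 2 arrays of high control ratio and the fit with that ratio as a covariate were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.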

Results

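Liver gene expression was measured in male Sprague Dawley rats given bis(2-ethylhexyl) tetrabromophthalate (TBPH), a brominated flame retardant that is the ring-brominated relative of the phthalate plasticiser DEHP. TBPH in corn oil was given by oral gavage on 5 consecutive days, and the left liver lobe was taken the day after the last dose. Per the labels the 36 arrays fall into 6 groups of 6 arrays, with TBPH at 706, 70.6, 7.06, 0.71 and 0.07 mg/kg and vehicle alone. Each array gives 1 log2 RMA value for each of 31042 probe sets that are not array controls, from 1.86 to 14.77 with a median of 5.09. Arrays give no counts, so the number of arrays limits the precision. The series title asks which liver transcripts change after this exposure, and its design text compares vehicle with each dose at a false discovery rate of 5%.

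The 6 dose groups were not set apart in their overall liver profile. Pairwise correlations between arrays across probe sets ran from 0.987 to 0.996 with a median of 0.994, where probe sets are not independent replicates. Group membership accounted for 12.3% of the variance over all probe sets, against 14.3% for random grouping (permutation test, p = 0.981). For single doses against vehicle the smallest exact permutation p of this kind was 0.299, at 70.6 mg/kg, before adjustment over 7 tests. Medians, interquartile ranges, control-gene ratios and the first and second principal components did not differ between groups by more than the spread within them (permutation tests over 6 measures, smallest p = 0.682). Quantile normalization makes medians and interquartile ranges largely alike beforehand, so these measures say little about the groups. Replicate 5 at 70.6 mg/kg and replicate 4 at 0.07 mg/kg stood apart on the first component, with scores of 37.5 and 32.9 against at most 11.96 on the other arrays. The same arrays had the highest 3′ to 5′ differences of the GAPDH control probe sets, 0.41 and 0.33 log2 against at most 0.09 elsewhere.

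**Figure D1:**
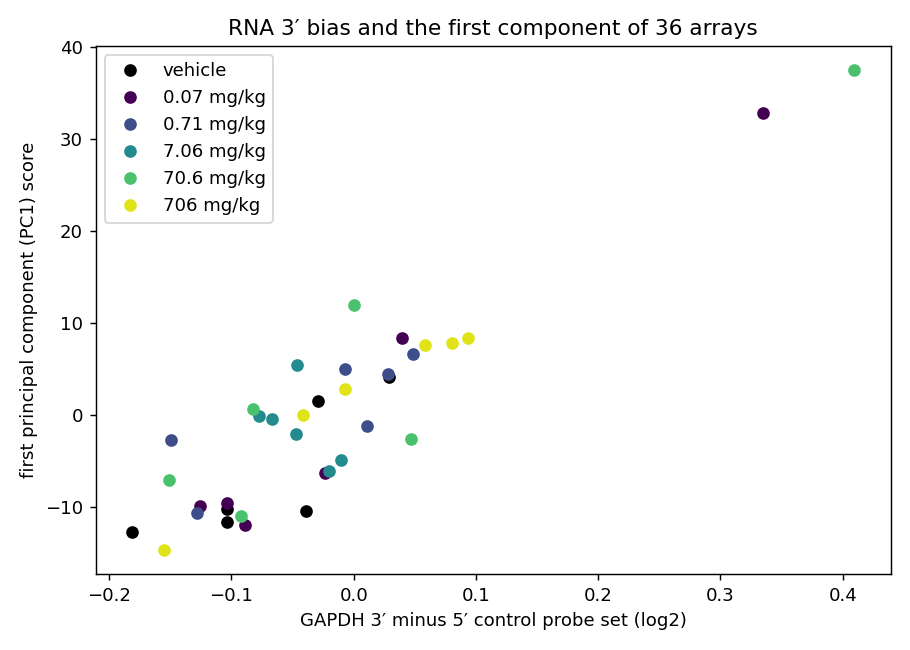
Each point is 1 of the 36 arrays, coloured by dose group; the x axis is the GAPDH 3′ minus 5′ control value (log2) and the y axis the score on the first principal component. 2 arrays, 1 at 70.6 mg/kg and 1 at 0.07 mg/kg, lie at scores of 37.5 and 32.9, and the other arrays of all 6 groups overlap.

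At 706 mg/kg, the highest dose, no gene could be called higher or lower than in vehicle, and this includes genes known to respond to phthalate esters in rat liver. Cyp4a1, a fatty acid omega-hydroxylase induced through the receptor PPAR alpha, averaged 11.45 ± 0.19 (SD, n = 6) against 11.29 ± 0.31 in vehicle (SD, n = 6), a log2 difference of 0.17 with a 95% interval of -0.14 to 0.47. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, averaged 11.37 ± 0.10 (SD, n = 6) against 11.16 ± 0.11 (SD, n = 6), a difference of 0.21 (0.02 to 0.40) that did not pass the adjusted threshold. Mki67, a marker of dividing cells, differed by 0.53 (0.04 to 1.02), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -0.40 (-1.38 to 0.59); neither passed. With limma, 0 of 31042 probe sets had an adjusted p under 0.05, and 1080 had an unadjusted p under 0.05, 412 higher and 668 lower, where 5% of the probe sets is 1552.1. The 95% interval excluded a change of more than 2-fold for 99.6% of the probe sets and of more than 1.5-fold for 97.7%. These shares include dim probe sets near the floor, where a narrow interval says little about the transcript.

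Among genes of lipid metabolism, the PPAR alpha targets lay slightly higher at 706 mg/kg as a group. Of 43 measured members 35 were higher and 8 lower, with a median log2 difference of 0.05 (camera, adjusted p = 0.0034); the adjusted p was 0.995 with an estimated correlation, and no member passed over all probe sets or when adjusted over the list alone. Members with the smallest p were Eci1 (0.31, 95% interval 0.10 to 0.52) and Acot2 (0.22, 0.05 to 0.38), enzymes of mitochondrial fatty acid oxidation and acyl-CoA hydrolysis. Acot1 differed by 0.03, Cpt1a, which brings fatty acids into mitochondria, by -0.05, and Pdk4, a kinase that spares glucose in fasting, by 0.25 (-0.23 to 0.73). Of 21 measured genes of cholesterol biosynthesis 19 were higher and 2 lower, with a median of 0.15 (adjusted p = 0.00167; adjusted p = 0.995 with an estimated correlation). Its members with the smallest p were Idi1 (0.38, 0.0027 to 0.76) and Lss (0.27, -0.04 to 0.58), and Sqle, the squalene epoxidase of the pathway, differed by 0.33 (-0.12 to 0.77). The PPAR alpha call ended without vehicle replicate 3 (adjusted p = 0.096), and the cholesterol call without replicate 1 or 3 at 706 mg/kg (adjusted p = 0.119 and 0.148). Fatty acid and triglyceride synthesis genes were split, 12 higher and 11 lower, with a median of 0.01 (adjusted p = 0.70); Mlxipl differed by 0.18, Acss2 by 0.25, Fasn by 0.12 and Thrsp by -0.17. Bile acid synthesis and transport genes had a median of -0.0027 (adjusted p = 0.986), with Cyp7b1 at -0.23 and the bile salt export pump Abcb11 at 0.14.

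Among lists of drug metabolism and its regulators, only the targets of the constitutive androstane and pregnane X receptors were called at 706 mg/kg. They were higher in 19 and lower in 6 of 25 measured members, with a median of 0.13 (camera, adjusted p = 0.00211; adjusted p = 0.995 with an estimated correlation), and the call ended without vehicle replicate 1 (adjusted p = 0.122). Ephx1, the microsomal epoxide hydrolase, differed by 0.24 (0.05 to 0.42) and the carboxylesterase Ces2c by 0.18 (-0.03 to 0.39), while Cyp3a23-3a1, a classical pregnane X receptor target, differed by 0.05 (-0.19 to 0.28). Aryl hydrocarbon receptor targets had a median of -0.02, with 5 higher and 5 lower (adjusted p = 0.688): Cyp1a1 differed by -0.05 (-0.27 to 0.16), Cyp1a2 by -0.06, Cyp1b1 by -0.11 and Aldh3a1 by -0.10. The NRF2 antioxidant list had a median of 0.03 (adjusted p = 0.142), with Gsta3 at 0.43 (-0.09 to 0.96) and Nqo1 at 0.03. Xenobiotic conjugation enzymes had a median of 0.04 (adjusted p = 0.142), with the glutathione transferase Gstt1 at 0.20 and the sulfotransferase Sult1a1 at -0.21. Carboxylesterases and lipases, the kind of enzyme that cleaves phthalate diesters, had a median of 0.02 (adjusted p = 0.954), with Ces1c at 0.11.

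Cell cycle genes were the remaining list called at 706 mg/kg: 31 of 39 measured members were higher and 8 lower, with a median of 0.12 (camera, adjusted p = 0.00259; adjusted p = 0.995 with an estimated correlation). The mitotic cyclin Ccnb1 differed by 0.60 (0.08 to 1.11) and Tk1, the thymidine kinase of S phase, by 0.18 (0.02 to 0.35). Leaving out vehicle replicate 3 or 4, or replicate 4 or 5 at 706 mg/kg, ended the call (adjusted p from 0.0678 to 0.336). The p53 and DNA damage list had a median of 0.01 (adjusted p = 0.96), with Tp53inp1 at -0.16 and Cdkn1a, the cell cycle inhibitor p21, at 0.19. Endoplasmic reticulum stress genes had a median of 0.02 (adjusted p = 0.763), with Atf3 at 0.41 and Atf4 at 0.17. The immediate early list, genes that respond within minutes to handling and stress, had a median of 0.09 (adjusted p = 0.204), with Klf6 at 0.33 and Jun at 0.46.

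None of the lists of hormone-responsive and rhythmic genes was called at 706 mg/kg. Thyroid hormone responsive genes had a median of -0.0021 (adjusted p = 0.986), with the deiodinase Dio1 at -0.0021, Hr at -0.14 and Igfals at 0.27. The growth hormone and sex-biased list had a median of 0.03 (adjusted p = 0.693), with the male-specific Cyp2c11 at -0.10 (-0.20 to 0.01) and Hsd17b2 at 0.38. Gluconeogenesis and fasting genes had a median of -0.01 (adjusted p = 0.142), with the urea cycle enzyme Ass1 at -0.15 and the leptin receptor Lepr at -0.26. Circadian clock genes had a median of 0.03 (adjusted p = 0.986): Bhlhe41 differed by -0.22, Dbp by -0.04 and Per2 by -0.09. The mean correlation between clock genes within groups was -0.0194. Such a mean does not show whether members varied in opposite directions, and opposite shifts could cancel in their median. Acute phase genes had a median of -0.0048 (adjusted p = 0.627), with Apcs at -0.09 and C3 at 0.07. Pericentral and periportal genes had a median of -0.04 (adjusted p = 0.149), with Aldh1b1 at 0.35. Mitochondrial respiratory chain genes had a median of 0.01 (adjusted p = 0.986), with Cox4i1 at 0.09 and Ndufa2 at 0.13. Ribosomal protein genes had a median of -0.01 (adjusted p = 0.438), with Rpl14 at -0.07 and Rpl18 at -0.09.

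Markers of other cell types did not shift past the threshold at 706 mg/kg. Stellate cell and fibroblast markers were higher in 19 of 20 members with a median of 0.13 (adjusted p = 0.0635); Lum, a proteoglycan of connective tissue, differed by 0.95 (-0.19 to 2.09) and Hgf by -0.25. Interferon response genes were higher in 24 of 27 members with a median of 0.18 (adjusted p = 0.0869), with Oas1b at 0.28 and Ifit1 at -0.21. Kupffer cell markers had a median of 0.01 (adjusted p = 0.96), with Folr2 at -0.19 and Csf1r at 0.14, and sinusoidal endothelial markers a median of -0.0022 (adjusted p = 0.846), with Stab1 at 0.23 and Flt1 at -0.15. Hepatocyte markers had a median of -0.01 (adjusted p = 0.728; Tdo2 -0.12, Apoa1 -0.10), and cholangiocyte markers a median of 0.02 (adjusted p = 0.986; Krt7 -0.14, Ggt1 0.14). Lymphocyte markers had a median of 0.02 (adjusted p = 0.986; Cd8b -0.09, Cd79b -0.10) and neutrophil and monocyte markers a median of 0.06 (adjusted p = 0.738), with Ccr2 at -0.22 and Defa5 at -0.18. Erythroid markers had a median of -0.06 (adjusted p = 0.212; Rhag -0.16, Epb42 -0.15), and markers of pancreas, gut, fat and muscle a median of -0.03 (adjusted p = 0.419), with Tnnt3 at -0.14 and Ctrb1 at -0.14. The named genes with the smallest p at this dose were Btnl3 (-0.30), Nectin4 (-0.30) and Bfsp2 (-0.29), all dim on these arrays, with vehicle means of 3.02, 4.47 and 4.55.

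**Figure D2:**
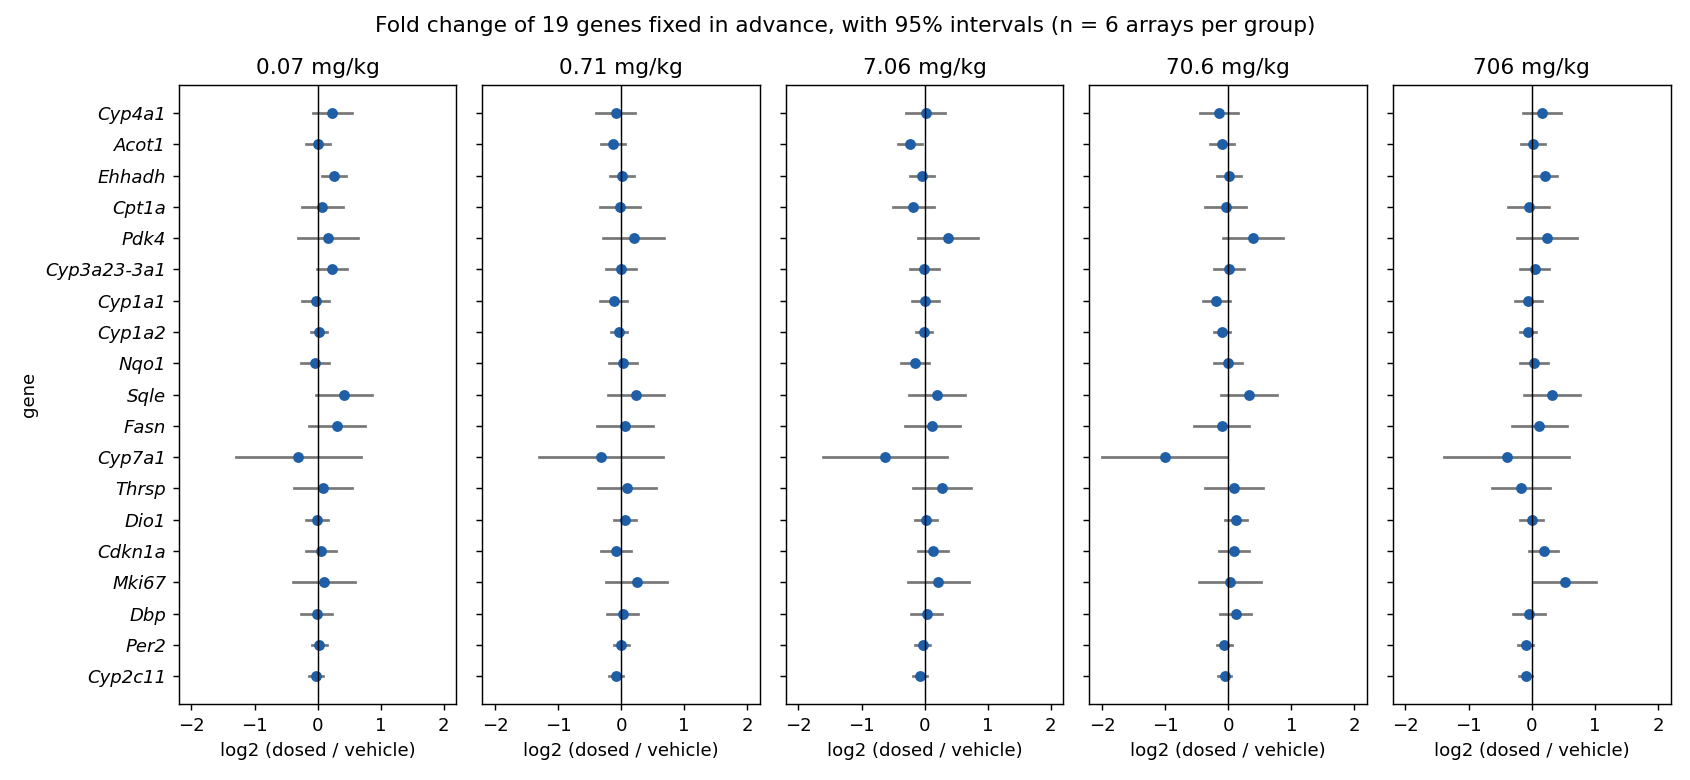
Points are log2 fold changes against vehicle of 19 genes chosen before the data were examined, with 95% intervals as bars, 1 panel per dose and 6 arrays per group. Most intervals cross 0, and Cyp7a1 has the widest, from -1.38 to 0.59 at 706 mg/kg.

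At 70.6 mg/kg the bile acid enzyme Cyp7a1 had the largest difference among the 19 panel genes, 9.54 ± 0.68 (SD, n = 6) against 10.55 ± 0.66 in vehicle (SD, n = 6). Its log2 difference of -1.01 had a 95% interval of -1.99 to -0.02 and an adjusted p of 0.921, so it did not pass. Pdk4 differed by 0.39 (-0.09 to 0.87) and Sqle by 0.33 (-0.11 to 0.77), while Cyp4a1 differed by -0.14 and Ehhadh by 0.01. Among named genes the smallest p belonged to Sfrp1, a secreted inhibitor of Wnt signalling (-0.32, -0.47 to -0.18), Folr1, a folate receptor (-0.30, -0.45 to -0.16), and Foxq1, a forkhead factor (0.39, 0.20 to 0.59), with adjusted p of 0.687, 0.687 and 0.735; the smallest adjusted p of any probe set was 0.632. With limma 0 probe sets were called and 1626 had an unadjusted p under 0.05, 752 higher and 874 lower, the only dose at which this count exceeded 1552.1. Without replicate 5 at this dose or another single array the call count stayed at 0.

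Immediate early genes gave the largest group shift at 70.6 mg/kg, with 14 of 19 measured members higher, 5 lower and a median of 0.30 (camera, adjusted p = 0.000888; adjusted p = 0.995 with an estimated correlation). On the mean of the list, 4 of the 6 dosed arrays lay above all 6 vehicle arrays (exact permutation p = 0.0173, and 0.277 after adjustment over the 16 called pairs). None of its members passed over all probe sets. Adjusted over the list alone, Klf6 (0.55) and Ier3 (0.70) did. Over all 155 pairs of list and dose only 5 members passed in this way, so chance cannot be excluded for them. In the growth hormone list, which was not called, Cish, an inhibitor of cytokine signalling through STAT5 (1.58), and Hsd17b2, a steroid dehydrogenase (0.56), passed when adjusted over the list alone, each with an adjusted p of 0.921 over all probe sets. Interferon response genes were higher in 24 and lower in 3 of 27 members, with a median of 0.28 (adjusted p = 0.0074; adjusted p = 0.995 with an estimated correlation); the chemokine Cxcl9 differed by 0.62 and the immunoproteasome subunit Psmb9 by 0.57. Replicate 5 at this dose had the highest interferon list mean of all arrays and a high 3′ to 5′ control difference, and without it the adjusted p was 0.209. The interferon call also ended without vehicle replicate 2 or 3 or replicate 4 at this dose (adjusted p from 0.0782 to 0.305), and when dim probe sets were left out (adjusted p = 0.0635). Cholesterol biosynthesis genes were higher in 19 and lower in 2 of 21 members, with a median of 0.19 (adjusted p = 0.00259; adjusted p = 0.995 with an estimated correlation), including Stard4 at 0.45 and Idi1 at 0.38; the call ended without replicate 2 at this dose (adjusted p = 0.0614).

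At 7.06 mg/kg no gene passed, and the 2 called group shifts were downward. Interferon response genes were lower in 22 and higher in 5 of 27 members, with a median of -0.17 (camera, adjusted p = 0.00864; adjusted p = 0.995 with an estimated correlation); Mx2 differed by -0.44 and Usp18 by -0.40. Kupffer cell and macrophage markers were lower in 15 and higher in 2 of 17 members, with a median of -0.09 (adjusted p = 0.0375; adjusted p = 0.995 with an estimated correlation), including Adgre1 at -0.23 and Cd5l at -0.22. Both calls ended without vehicle replicate 1 or 5, or without replicate 1, 3 or 4 at this dose, and the interferon call also without vehicle replicate 4; the adjusted p then ran from 0.0574 to 0.515. The Kupffer cell call also ended with all probe sets of each member (adjusted p = 0.071). The B cell marker Ms4a1 (-0.38) passed when adjusted over the lymphocyte list alone, with an adjusted p of 1.00 over all probe sets. Panel genes lay between -0.63 (Cyp7a1, -1.61 to 0.36) and 0.37 (Pdk4, -0.11 to 0.85), with Cyp4a1 at 0.02, Cyp1a1 at 0.01 and Sqle at 0.19. Among named genes the smallest p belonged to Fbxo3 (-0.42), Zp2 (-0.32) and Mical3 (0.44). With limma 0 probe sets were called and 1079 had an unadjusted p under 0.05, 341 higher and 738 lower.

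At 0.71 mg/kg the smallest camera p belonged to stellate cell and fibroblast markers, higher in 18 and lower in 2 of 20 members. Their median was 0.18 (camera, adjusted p = 6.99e-05, and 0.995 with an estimated correlation). On the mean of this list, the exact permutation p was 0.149, and 0.450 after adjustment over the 16 called pairs. The collagens Col1a2 and Col3a1 differed by 0.40 and 0.28, and the smooth muscle gene Tagln by 0.75. Interferon response genes were higher in 23 and lower in 4 of 27 members, with a median of 0.22 (adjusted p = 0.00708; adjusted p = 0.995 with an estimated correlation), including Mx2 at 0.66 and Cxcl9 at 0.57. Cholesterol biosynthesis genes were higher in 18 and lower in 3 of 21 members, with a median of 0.16 (adjusted p = 0.0268; adjusted p = 0.995 with an estimated correlation). The interferon call ended without vehicle replicate 2 or 3 or replicate 3 or 6 at this dose (adjusted p up to 0.345), and the cholesterol call without vehicle replicate 1, 2 or 3 or replicate 1, 2, 4 or 6 at this dose (adjusted p up to 0.177). Leaving out dim probe sets ended both calls too (adjusted p = 0.0558 and 0.0876). Panel genes lay between -0.32 (Cyp7a1) and 0.25 (Mki67), with Cyp4a1 at -0.09 and Ehhadh at 0.02. Among named genes the smallest p belonged to Ppp3r1, a calcineurin subunit (-0.32), Taf3 (0.32) and Itga8 (0.30). With limma 0 probe sets were called and 1235 had an unadjusted p under 0.05, 450 higher and 785 lower.

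At 0.07 mg/kg, the lowest dose, cholesterol biosynthesis genes gave the smallest adjusted p of any list at any dose, with 20 members higher, 1 lower and a median of 0.22 (camera, adjusted p = 1.61e-09; adjusted p = 0.995 with an estimated correlation). These genes varied together within groups (mean correlation 0.505), while camera's preset was 0.01. On the mean of the list, 2 of the 6 dosed arrays lay above all 6 vehicle arrays. The exact permutation p was 0.0909, and 0.450 after adjustment over the 16 called pairs. Acat2 differed by 0.56, Idi1 by 0.45 and Sqle by 0.42 (-0.02 to 0.86). PPAR alpha targets were higher in 32 and lower in 11 of 43 members, with a median of 0.05 (adjusted p = 0.00864; adjusted p = 0.995 with an estimated correlation), with Ehhadh at 0.26 (0.07 to 0.44) and Cyp4a1 at 0.23 (-0.07 to 0.54). Constitutive androstane and pregnane X receptor targets were higher in 22 and lower in 3 of 25 members, with a median of 0.07 (adjusted p = 0.0216; adjusted p = 0.995 with an estimated correlation), with Cyp3a23-3a1 at 0.23 (-0.01 to 0.46). Fatty acid and triglyceride synthesis genes were higher in 19 and lower in 4 of 23 members, with a median of 0.08 (adjusted p = 0.0137; adjusted p = 0.995 with an estimated correlation), with Acss2 at 0.44 and Fasn at 0.31 (-0.13 to 0.75). Without replicate 4, the array of this dose with a high 3′ to 5′ control difference, the receptor list and the fatty acid list were no longer called (adjusted p = 0.121 and 0.352). The PPAR alpha call ended without vehicle replicate 1, 3 or 6 or replicate 3 or 6 at this dose, the receptor call also without vehicle replicate 1 or 6 or replicate 6 at this dose, and the fatty acid call also without vehicle replicate 2 or 3 or replicate 5 at this dose (adjusted p from 0.0741 to 0.391). Among named genes the smallest p belonged to Cpsf7 (-0.31), Nxph1 (-0.32) and Zswim4 (0.28). With limma 0 probe sets were called and 953 had an unadjusted p under 0.05, 387 higher and 566 lower.

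**Figure D3:**
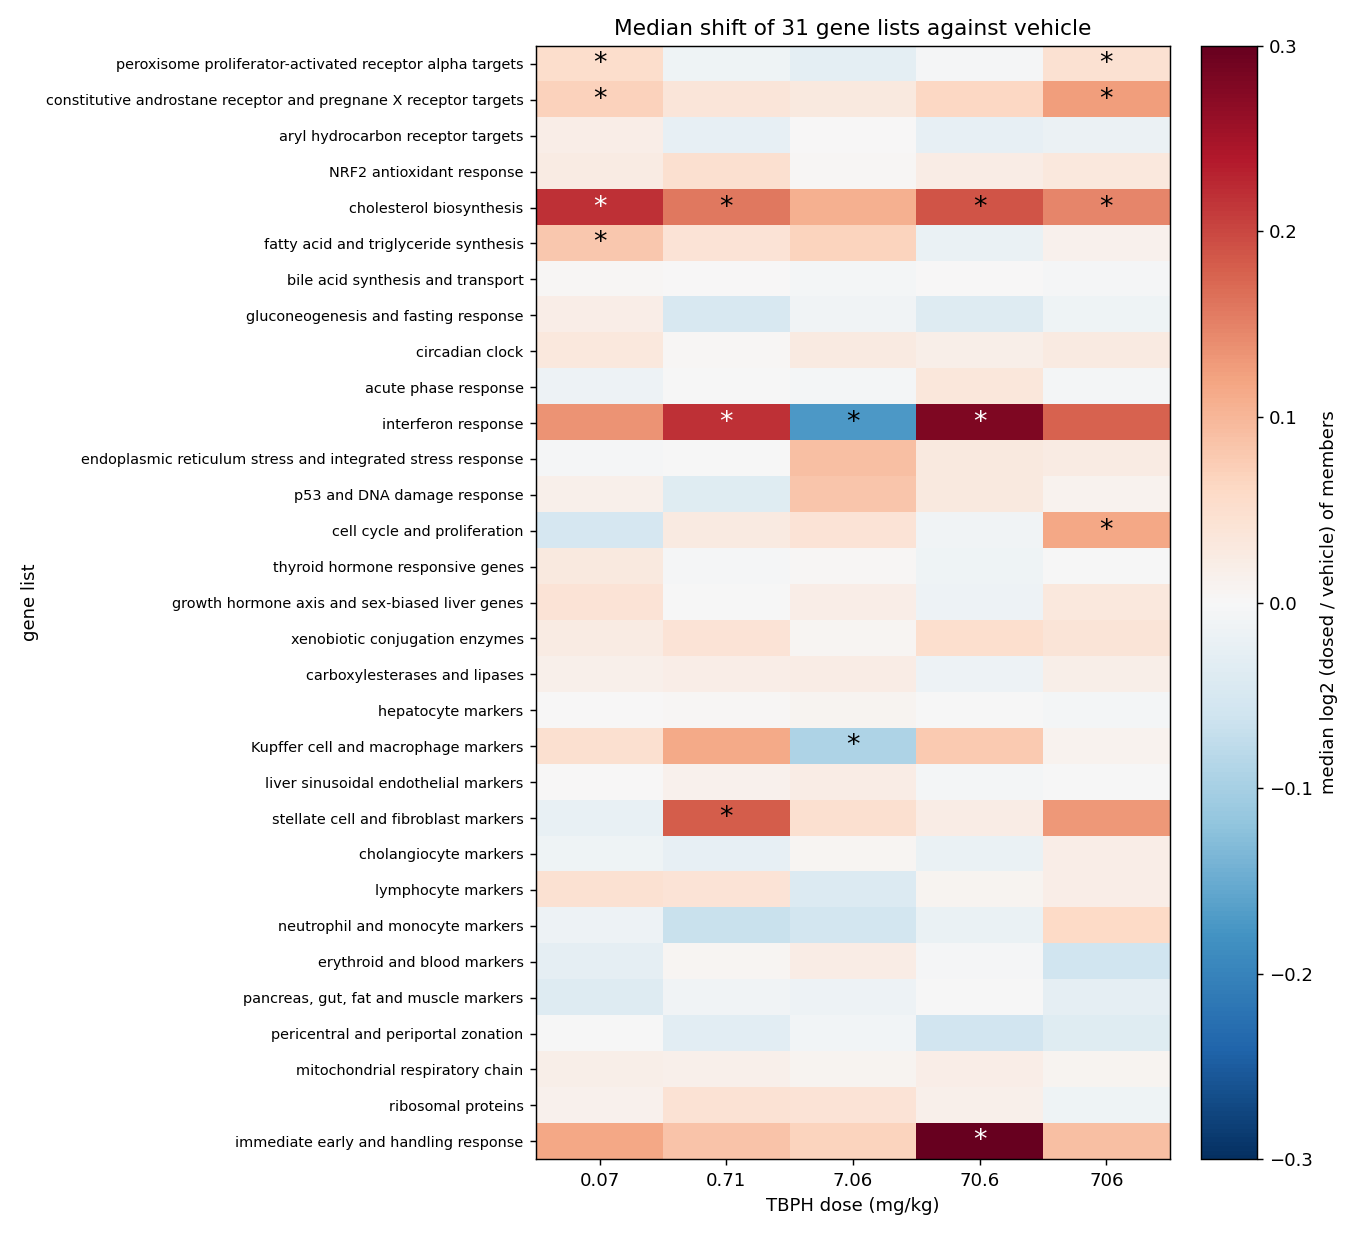
Colour gives the median log2 difference from vehicle of the measured members of each of 31 gene lists (vertical axis) at each dose (horizontal axis), and asterisks mark the 16 list and dose pairs called by camera with the preset correlation, of which 0 were called with an estimated correlation. Cholesterol biosynthesis is marked at 0.07, 0.71, 70.6 and 706 mg/kg, each compared with the same vehicle arrays, so these marks are not independent.

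Across doses no gene followed the dose past the threshold. Among named genes, for the slope over dose rank, Btnl3 had the smallest p at -0.05 log2 per step, followed by Folr1 (-0.05), C10h17orf75 (-0.08), Zp2 (-0.05), Prox1 (-0.06), Scai (0.05), Arhgef10 (-0.03), Rpe65 (-0.04), Nalf1 (-0.05) and Tekt3 (-0.04), each with an adjusted p of 0.998; limma called 0 probe sets and 1292 had an unadjusted p under 0.05. For any difference among the 6 groups, the smallest p of named genes belonged to Nxph1, Sfrp1, Mir29c, Edrf1, Acot2, Rab40b, Zfhx2, Taf3, Cxcl13 and Nlgn2, each with an adjusted p of 1.00; limma called 0 and 788 had an unadjusted p under 0.05. Between 706 and 70.6 mg/kg limma called 0 probe sets, with 1041 at an unadjusted p under 0.05 and a smallest adjusted p of 0.89. As no dose had calls, no overlap between doses could be counted. Comparisons pooling doses were added after seeing the data: all 5 doses against vehicle gave 0 calls with 1287 at an unadjusted p under 0.05, and the 70.6 and 706 mg/kg groups together gave 0 calls with 1434.

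In most of the called lists no trend over dose was called. Cholesterol biosynthesis genes had medians of 0.22, 0.16, 0.11, 0.19 and 0.15 from the lowest to the highest dose. Their upward trend over dose rank was not called (camera, unadjusted p = 0.033, adjusted p = 0.147). Interferon response genes had medians of 0.13, 0.22, -0.17, 0.28 and 0.18 (adjusted p for the trend 0.264). All doses share the same vehicle arrays, so a low vehicle mean in a list would raise its medians at every dose. Calls of the same list at several doses are therefore not independent of each other. A trend over dose rank, also added after seeing the data, was called upward for cell cycle genes (camera, adjusted p = 0.03), for constitutive androstane and pregnane X receptor targets (adjusted p = 0.0494) and for immediate early genes (adjusted p = 0.0494), and for 0 lists with an estimated correlation (adjusted p = 0.926, 0.692 and 0.692). Over all lists and doses camera called 16 of 155 pairs, 14 upward and 2 downward in 9 lists, against 0 with an estimated correlation and 0 with fry, each with 3 pairs at an unadjusted p under 0.05. In random splits of the arrays camera called a median of 20 pairs, more than the real 16. Of the 16 called pairs, 3 kept the call without any single array: cholesterol biosynthesis at 0.07 mg/kg, stellate cell markers at 0.71 mg/kg and immediate early genes at 70.6 mg/kg. In exact permutation tests of the list mean their adjusted p was 0.450, 0.450 and 0.277, so none passed.

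**Figure D4:**
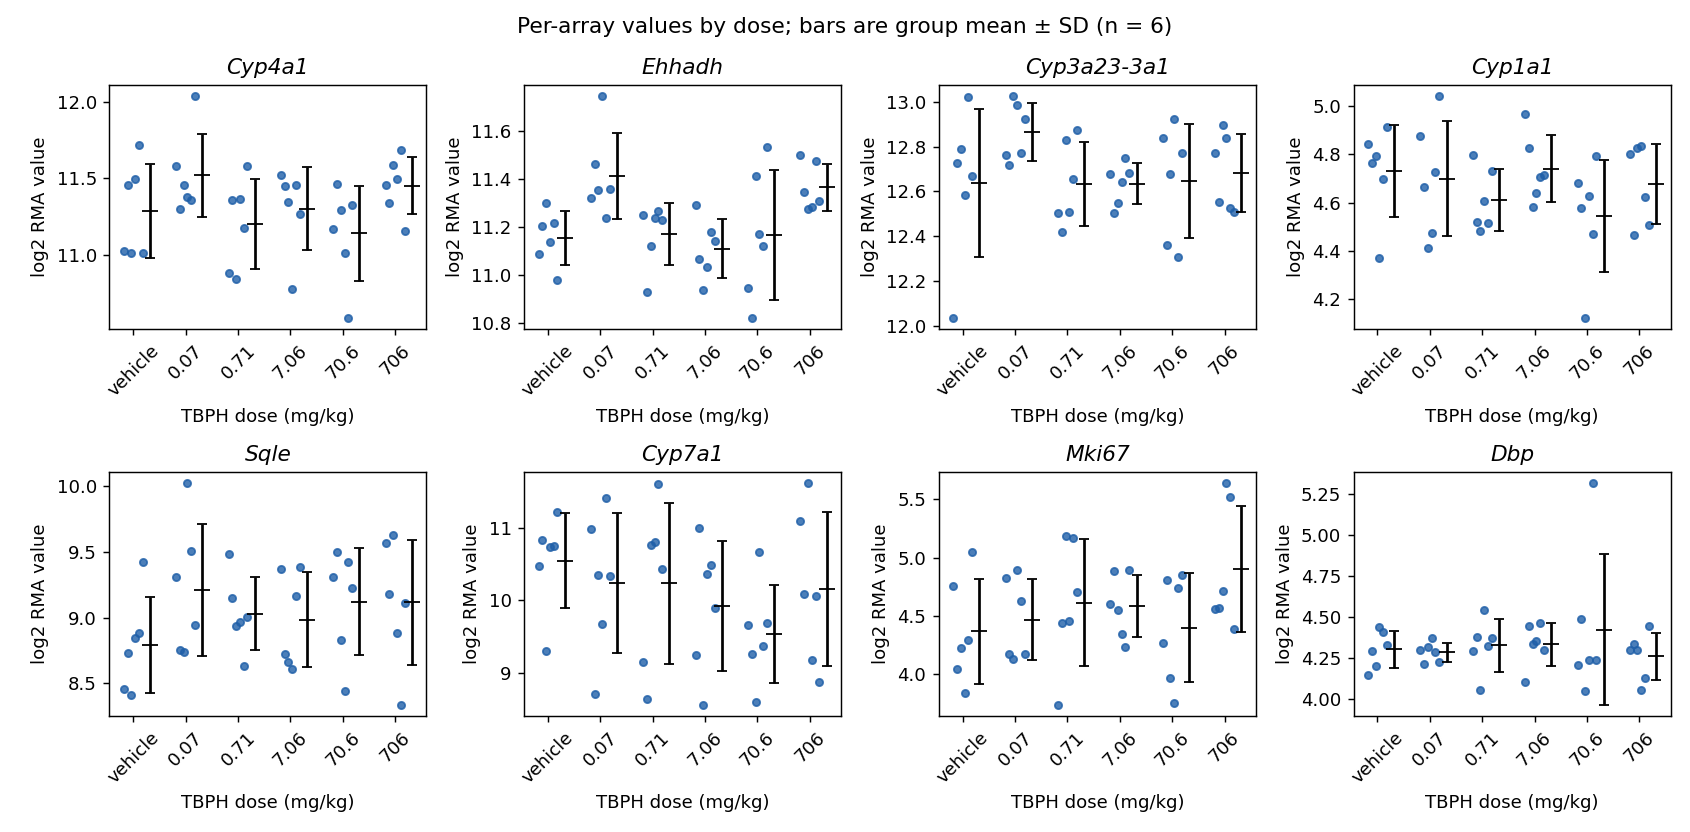
Points are log2 RMA values of single arrays for 8 genes (y axis) by dose group (x axis), with the group mean ± SD as bars (n = 6). Cyp7a1 spans more than the differences between its group means, and Dbp has 1 high array at 70.6 mg/kg, at 5.32.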

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

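The tests of RNA integrity, dose and clock genes on the 2 arrays that stood apart were chosen only after the result was seen; the checks for single far arrays and the random splits were not.

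Single arrays were picked out where the gap to the nearest array of the same group over the range of the 6 arrays exceeded Dixon's critical value at the 95% level. Of 234 such checks 11 did so, where chance alone gives about 1 in 20, or 11.7. In replicate 4 at 0.07 mg/kg the 3′ to 5′ control differences were high, with gap ratios of 0.641 for GAPDH and 0.699 for actin, and in replicate 5 at 70.6 mg/kg the ratios were 0.647 and 0.634. In that same array at 70.6 mg/kg the clock output gene Dbp was high, at 5.32 against at most 4.49 (0.654). Replicate 4 at 7.06 mg/kg was low in Cyp4a1, at 10.78 against at least 11.27 (0.656), and in its interquartile range (0.653). Replicate 6 at 0.07 mg/kg was low in its interquartile range (0.729). Replicate 3 at 706 mg/kg was low in Cyp1a2, at 12.79 against at least 13.02 (0.842), and on the first component (0.64). In vehicle, replicate 5 was high in the calcineurin subunit Ppp3r1, at 4.45 against at most 4.17 (0.669).

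Replicate 5 at 70.6 mg/kg and replicate 4 at 0.07 mg/kg stood apart on the first component, with scores of 37.5 and 32.9. Over 36 arrays with group means removed, the GAPDH 3′ to 5′ difference rose with the first component (r = 0.931, rho = 0.839, each with a permutation p of 1e-05, the smallest the permutations can give, and 2e-05 after adjustment over 4 relations), and r was 0.839 without these 2 arrays, so a difference in RNA integrity may account for the component. The clock list score did so less firmly (r = 0.653, permutation p = 0.00011, adjusted 0.000147, and rho = 0.39, permutation p = 0.019, adjusted 0.0253). Without the 2 arrays r was 0.295 (permutation p = 0.0905, adjusted p = 0.121), so whether the relation holds in the other arrays stays open. The score is a plain mean of genes whose mean correlation within groups was -0.0194, which does not show whether they varied in opposite directions. Opposite shifts can cancel in such a score, so it cannot decide on a time-of-day or feeding difference, which stays open. The other 10 arrays of the same groups differed from the 24 arrays of the remaining groups by -2.33 on this component (95% interval -8.74 to 4.09), where the nearer of the 2 arrays lay 34.3 above those 24, against dose moving all arrays of a group; an effect of dose in single arrays was not tested. The actin difference gave r = 0.88 and rho = 0.749 with the first component (each permutation p = 1e-05, adjusted 2e-05) and r = 0.729 without the 2 arrays, and GAPDH against the clock score r = 0.558 (p = 0.00219), rho = 0.216 (p = 0.206) and r = 0.0867 without them.

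Random splits of the arrays decide nothing for the counts of called probe sets: with a real count of 0 in each comparison, all 100 of 100 splits must give at least as many. The highest other count was 18 at 0.07 mg/kg, 2 at 0.71, 0 at 7.06, 1 at 70.6 and 2 at 706 mg/kg, 4 for the slope, 4 for any difference, 3 for 706 against 70.6 mg/kg, 5 for all doses pooled and 7 for the highest doses pooled. For counts at an unadjusted p under 0.05, as many were found in 88 of 100 splits at 0.07 mg/kg (real 953, highest other 2988), 71 at 0.71 (1235, 3085), 40 at 7.06 (1079, 1934), 45 at 70.6 (1626, 3968), 60 at 706 mg/kg (1080, 3192) and 67 for the slope (1292, 3882), so chance cannot be excluded for these counts. The highest splits, such as 2988 against 953 at 0.07 mg/kg, may point to a structure among the arrays, which was not tested; the median of the other splits was nearer the real count, 1438 at 0.07 and 1149 at 706 mg/kg. For the gene lists, 76 of 100 splits called at least the real 16 pairs. The median of the other splits was 20 and the highest 41, so chance cannot be excluded for the number of list calls. Camera with the preset correlation called that many pairs in relabelled arrays too, so its adjusted p overstates the evidence for these lists.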

How the results depend on the processing

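The fits without the 2 arrays of high control ratio, with that ratio as a covariate and with pooled doses were chosen only after the result was seen, the others before. The count of called probe sets was 0 for all 10 comparisons under every adjusted threshold run, with adjusted p as low as 0.105, and stayed from 0 to 0 when each of 36 arrays was left out in turn. Only an unadjusted p under 0.005 with a fold of at least 1.5 gave other counts: 11 at 70.6 mg/kg, 1 at 706 mg/kg, 2 for the slope, 1 for any difference and 1 for 706 against 70.6 mg/kg; the fold of the slope was taken over all 5 dose steps and that of any difference from the dose furthest from vehicle, and this threshold has no adjustment. Of 4241 recomputed values of named genes, 154 took the other sign and 0 passed. The list calls moved from 16 to 0 with an estimated correlation, to 0 with fry and to 0 without the 2 arrays with an estimated correlation, where the preset correlation is 0.01 and the called lists have a median estimate of 0.345; without the 2 arrays alone 17 were called, 13 of them shared. Leaving out dim probe sets ended the interferon calls at 0.71 and 70.6 mg/kg (adjusted p = 0.0558 and 0.0635) and the cholesterol call at 0.71 mg/kg (adjusted p = 0.0876), and taking all probe sets of each member ended the Kupffer cell call at 7.06 mg/kg (adjusted p = 0.071); the cause was not tested. These settings called more pairs in all, 18 without dim probe sets (13 shared) and 23 with all probe sets (15 shared), and the arrays of the 2 groups compared alone gave 21 (16 shared). Leaving out 1 array gave from 11 to 21 list calls, 11 without vehicle replicate 3. Of 704 recomputed shifts of called lists 103 were no longer called and 0 turned direction. The overlap with the vehicle arrays divided was not run, as there were no calls. Probe sets with means near the floor limit what can be seen: Acot1 averaged 2.81 in vehicle.

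Replicate numbers did not pair the arrays: same-number pairs had a mean correlation of -0.016. With the replicate number as a block the counts of probe sets were 0 in all comparisons and 17 list pairs were called, 16 of them shared.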

Other observations

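The tests of the genes that split the arrays and of the list calls were all chosen only after the result was seen, as were the genes named here.

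Some genes differed widely between liver arrays of the same dose group. Taking only the brightest probe set of each gene, the largest within-group SDs were those of Ugt2b (2.28 log2) and Abhd3 (1.87). Next were the class II histocompatibility genes RT1-Bb (1.68) and RT1-Ba (1.47) and the transcription factor Onecut1 (1.31). The median over all probe sets, with and without a symbol, was 0.147. The SD was 1.20 for Fgf21, a liver hormone of fasting, 1.18 for the repressor Bcl6, 1.17 for the metallothionein Mt2A, 1.10 for the immediate early factor Egr1 and 1.05 for Lum. Fgf21 ran from 5.84 to 10.14 and Mt2A from 7.20 to 11.36.

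Several gene groups varied together between arrays of 1 dose group. The mean correlation between members within groups was 0.631 for Kupffer cell markers, 0.618 for interferon response genes, 0.569 for ribosomal proteins, 0.505 for cholesterol biosynthesis and 0.464 for cell cycle genes. It was -0.0122 for hepatocyte markers, -0.0194 for clock genes and -0.023 for aryl hydrocarbon receptor targets.

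Lists called with the preset correlation had, at the median, members that vary together more. The 9 lists called at any dose had a median within-group correlation of 0.345 against 0.0695 in the other 22 (permutation p = 0.00099), so shared variation between arrays may account for part of the calls. Called and other lists overlapped: among called lists the correlation was 0.103 for constitutive androstane and pregnane X receptor targets, 0.14 for immediate early genes and 0.163 for PPAR alpha targets, while ribosomal proteins (0.569) and lymphocyte markers (0.223) were called at 0 doses. An effect of TBPH on these lists cannot be told apart from it: over the 16 called pairs, exact permutation tests of the list mean gave a smallest p of 0.0173, for immediate early genes at 70.6 mg/kg, and 0.277 after adjustment. That shift was 0.36 log2 with a 95% interval of 0.09 to 0.63, and 4 of 6 dosed arrays lay above all vehicle arrays.

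A few probe sets were split between a low and a high level from array to array. With a gap of more than 2 log2 and at least 3 arrays on each side, 6 probe sets split the 36 arrays: 5 of 4 named genes, Ugt2b with a pair of them, and 1 with several gene symbols, at 3.45 to 4.42 in 12 arrays and, after a gap of 5.59 log2, at up to 11.43 in 24. Ugt2b, an androsterone glucuronosyltransferase, was at 5.11 to 5.36 in 3 arrays (vehicle replicate 5, 0.07 mg/kg replicate 1 and 706 mg/kg replicate 3) and at 12.62 to 13.39 in the other 33. A probe set of RT1-Ba was at 4.44 to 5.20 in 3 arrays and at 8.18 or more in 33, and the ubiquitin-like gene Ubd at 4.59 to 5.08 in 3 and at 7.16 or more in 33. A probe set of Abhd3 was at 7.16 to 7.80 in 8 arrays and at most at 3.35 in 28. The gene's other probe set ran from 2.79 to 3.86 in all arrays. It is dim, with a mean of 3.28, so it cannot show whether the split holds for the gene.

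Dose as the whole source was argued against for all but RT1-Ba. At least 1 vehicle array was in the smaller set of Ugt2b, Ubd, Abhd3 and the probe set with several symbols, so both levels occur without TBPH. For RT1-Ba 0 of the 3 low arrays were vehicle, with 1 of 6 arrays low at each of 0.71, 70.6 and 706 mg/kg, and dose cannot be told apart with so few arrays. The adjusted permutation p for a group difference ran from 0.758 to 0.915 over 5 tests, which leaves a smaller effect of dose open.

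Of the low arrays, 4 were low in more than 1 set: all 3 of RT1-Ba and 1 of Ugt2b were also low in the probe set with several symbols. In 17 arrays Ugt2b, RT1-Ba, Ubd or that probe set was low. Each had at most 11 of 15521 brighter probe sets more than 2 log2 below the median of the other arrays. This is against low values over many probe sets of these arrays. Quantile normalization evens out a generally dim array beforehand, so such a failure could not be seen. The 11 were in replicate 5 at 70.6 mg/kg, which also had a high 3′ to 5′ control difference. Abhd3, low in most arrays, was not part of this test.

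A fault of 1 probe set was tested for Ugt2b alone, and a sequence variant under 1 probe set for RT1-Ba alone. For Ugt2b all 3 low arrays were also the lowest in the gene's other probe set, against 1 faulty probe set. For RT1-Ba the 3 low arrays were among the highest in the brightest other probe set, at ranks 33, 35 and 36 of 36 from the lowest (exact permutation p = 0.00056 over 7140 choices), against a sequence variant under 1 probe set alone, which would leave them at ordinary ranks there. The test covers only that case. Sequence variants that reach both probe sets were not tested and stay open. What sets these arrays apart stays open. Inherited variants in an outbred stock may underlie the splits, a hypothesis not tested, as the labels give no genotype.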
